A study of Mus musculus with 10 samples.

How the data were processed

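Total RNA from epididymal white adipose tissue of 10 mice was sequenced, 5 with adipocyte-specific loss of Sucnr1 and 5 floxed controls. Per the labels' protocols, RNA was extracted with TRIzol, cleaned on columns with DNase treatment, and 300 ng per sample entered a stranded total RNA library kit. The deposited values are raw counts per Ensembl gene, whole numbers with no normalization. Per the submitters' processing notes, STAR 2.5.2 and the mm10 build were used. The counting program, its annotation and its strand setting are not given in the sources used here, so overlapping and antisense genes are uncertain. Rpl29 and other ribosomal protein genes also have near-identical pseudogenes that can share reads.

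Each column of the table was matched to a sample by its title, and the groups came from the condition label. The labels do not say whether litter, cage, time of collection or diet was matched. Total counts ranged from 24182798 to 30603326 per library. Of 26040 gene identifiers, 2760 had no count in any library, and 25995 had a symbol in GENCODE mouse release M21, which supplied symbols and mm10 coordinates. Pairs of libraries were compared by a chi-square test of their counts, and no pair agreed within sampling noise.

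Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its minimum count of 10 and minimum total of 15, which left 16446 genes. Libraries were scaled by TMM, and the robust quasi-likelihood test was fitted with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values use the scaled library sizes, and log2 CPM values use a prior count of 2. Standard errors were derived from the fitted fold change and its F statistic. The common biological coefficient of variation was 0.412.

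A set of 36 gene lists was fixed before the data were examined, and 620 of their 670 distinct genes were tested. Each list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The mean log2 CPM of each list was compared by an exact two-sided permutation test over 252 assignments, whose smallest p is 0.00794. Members were also adjusted over the list alone. A hepatocyte list was added after the data were seen and served as a covariate.

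The genes named in the text follow a rule fixed before the data were examined. Sucnr1, Lep and every tested clock gene were named, together with up to 10 called genes per direction with a mean log2 CPM of at least 0, and up to 4 members with the smallest p from each list described. A gene that the rule takes is not reported here. Crisp1, Akr1b7, Alb, Adipoq and the further genes of chromosome 9 were chosen after their values were seen. Tat, Ahsg and Ucp1 also fall outside the rule.

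The steps were tested on simulated data with the libraries' own means, dispersions and depths. For knockout against control with 16446 genes, 8% of 50 genes changed 1.5-fold were recovered, as were 66% at 2-fold, 90% at 4-fold and 88% at 8-fold. Of 130 calls, 4 were false. A clock list planted with a uniform shift was recovered by camera, with 0 other lists called. Genes were drawn independently of each other, so the simulated lists held no correlation between members. The simulation therefore cannot show how often camera calls lists falsely in these libraries.

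Alternatives covered 3 other scalings, DESeq2 1.42.0, limma-voom with and without sample weights, other filters, a replicate block, a surrogate variable from sva 3.50.0, removal of mitochondrial and ribosomal RNA genes, and each library left out in turn. Added after seeing the data were marker scores as covariates and the removal of pairs of libraries with RNA of other tissues.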

Results

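RNA sequencing was carried out on epididymal white adipose tissue, the large visceral fat depot that lies against the epididymis of male mice. The knockout group held 5 libraries from C57BL/6 mice lacking the succinate receptor gene Sucnr1 in adipocytes, and the control group held 5 libraries from mice with floxed Sucnr1 alleles. Succinate is an intermediate of the tricarboxylic acid cycle that also acts outside cells through this receptor. The total count per library ranged from 24182798 to 30603326, and 16446 of the 26040 genes listed had enough counts to be tested. The comparison between the groups asks how loss of the receptor from adipocytes changes gene expression in this tissue.

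Sucnr1, the targeted gene, was low in every knockout library. It stood at 3.10 ± 1.01 CPM (counts scaled to library size; SD, n = 5) in the knockout group and at 59.6 ± 17.4 CPM (SD, n = 5) in the controls. The log2 fold change was -4.26 with a standard error of 0.29 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000333). The highest knockout library reached 4.67 CPM and the lowest control library 38.01 CPM, so the groups did not overlap, and an exact two-sided permutation test gave p = 0.00794, the smallest value that 5 against 5 libraries allow. Sucnr1 (ENSMUSG00000027762) lies on the plus strand of chromosome 3 from 60081869 to 60087566 in mm10. Its count covers the whole gene in whole tissue, where cells other than adipocytes also contribute RNA. Of 12 tested neighbours of Sucnr1 on chromosome 3, 7 were higher and 5 lower in the knockout group, none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.764).

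Across all genes, 10 passed an adjusted p of 0.05, of which 4 rose and 6 fell in the knockout group. Besides Sucnr1, the clock genes Per3, Tef and Arntl changed, as did Zfp949, Gsta4, Rpl29, Abhd14b, Ppm1m and Adamts4. Zfp949, a zinc finger gene, rose from 19.9 ± 1.9 to 53.2 ± 1.8 CPM (SD, n = 5 per group), a log2 fold change of 1.42 with a standard error of 0.08 (edgeR adjusted p = 6.8e-05). Gsta4, a glutathione S-transferase that conjugates products of lipid peroxidation, rose from 18.6 ± 3.8 to 48.7 ± 7.1 CPM (edgeR adjusted p = 0.0168). Rpl29, which encodes a protein of the large ribosomal subunit, fell from 21.2 ± 3.9 to 5.95 ± 0.75 CPM, a log2 fold change of -1.83 (edgeR adjusted p = 0.000676). Adamts4, a secreted protease that cleaves aggrecan, fell from 9.51 ± 2.58 to 3.59 ± 0.21 CPM (edgeR adjusted p = 0.0333).

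The 10 genes each separated the groups without overlap. In all, 314 tested genes did so, which is 1.91% against 0.794% by chance. At an unadjusted p under 0.05 there were 1667 genes. The number of calls depended on the test and on single libraries: DESeq2 called 211 genes, and leaving out 1 library gave between 3 and 18. Of the named genes outside the 10, 23 passed with DESeq2, and 3 passed in another fit: Cldn5, Per2 (adjusted p = 0.0184 with 1 surrogate variable) and Hlf (0.0114 with the adipocyte marker score as a covariate). Zfp949, Sucnr1 and Rpl29 passed in all 10 fits that left out 1 library, whereas Abhd14b passed in 5, Gsta4 in 4, Per3 in 3, Arntl and Tef in 2 each, and Adamts4 and Ppm1m in 1 each. With the adipocyte marker score as a covariate, Gsta4 (adjusted p = 0.0715), Arntl (0.0703) and Tef (0.0832) no longer passed.

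Of the 10 called genes, 5 lie on chromosome 9, namely Zfp949, Gsta4, Rpl29, Abhd14b and Ppm1m. Rpl29 (ENSMUSG00000048758) spans 106429454 to 106431568 on the plus strand, and Abhd14b (ENSMUSG00000042073) spans 106447459 to 106452923 on the same strand, where it overlaps Abhd14a on the other strand. Ppm1m (ENSMUSG00000020253), a protein phosphatase gene, lies close by on the minus strand from 106194947 to 106199746. Gsta4 (ENSMUSG00000032348) spans 78182774 to 78209349 and Zfp949 (ENSMUSG00000032425) spans 88548020 to 88571061, both on the plus strand. Chromosome 9 was singled out after these values were seen. It held 12 of the 53 genes with an unadjusted p under 0.001, against 2.95 from its share of tested genes (hypergeometric adjusted p = 0.000532 over 20 chromosomes), and 5 of the 12 were higher and 7 lower in the knockout group.

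**Figure D1:**
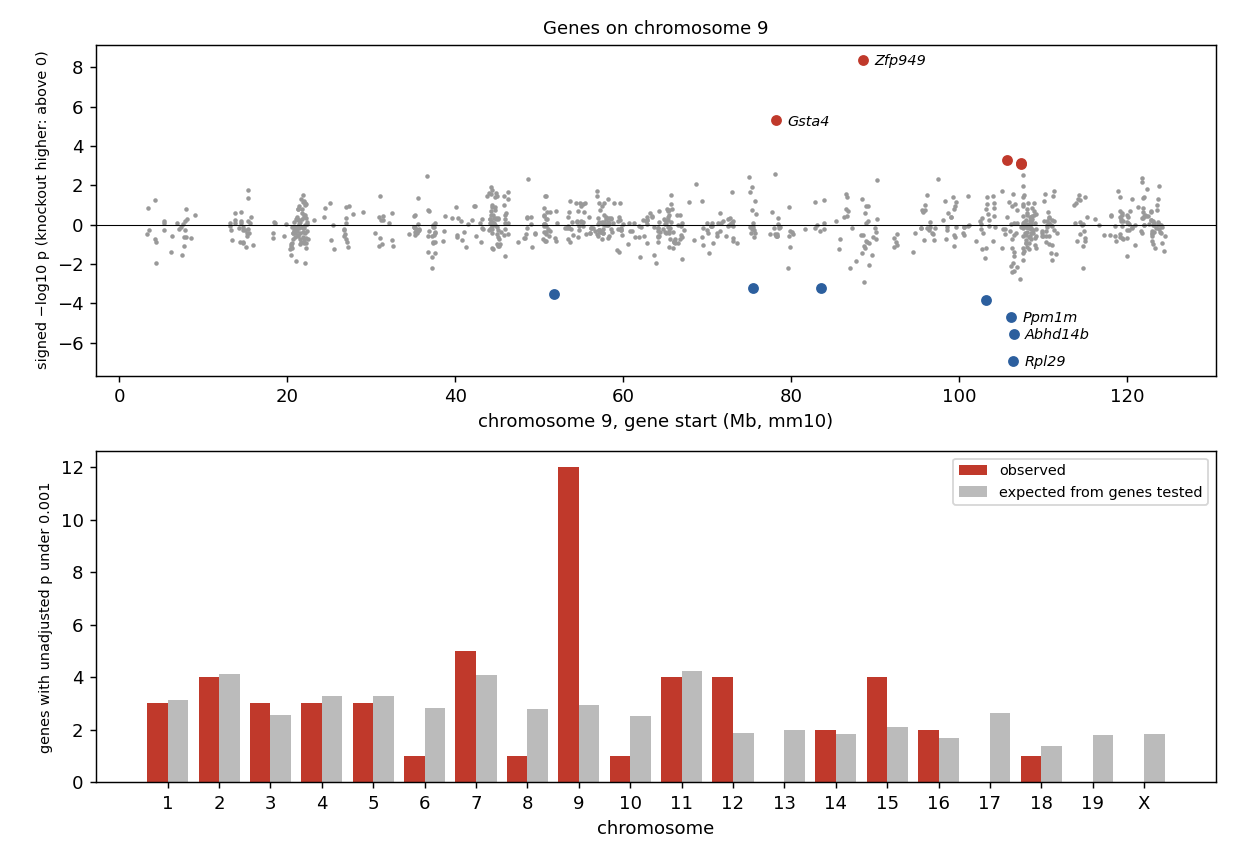
Signed −log10 of the unadjusted edgeR p for tested genes along chromosome 9 (above 0, higher in knockout; coloured points, p under 0.001), and the number of genes with p under 0.001 on each chromosome beside the number expected from the genes tested. Chromosome 9 held 12 such genes against 2.95 expected, and chromosome 7, the next, held 5.

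Genes of the circadian clock changed in both directions. Arntl, which encodes the activator BMAL1, fell from 21.5 ± 3.3 to 7.72 ± 1.92 CPM (log2 fold change -1.47, SE 0.18, edgeR adjusted p = 0.0202). Per3, a period gene of the repressing limb, rose from 133 ± 15 to 222 ± 14 CPM, and Tef, a transcription factor of the clock output, rose from 179 ± 17 to 298 ± 26 CPM (edgeR adjusted p = 0.0202 for each). All SDs are over n = 5 libraries per group.

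Of the 19 clock genes tested, 15 were higher and 4 lower in the knockout group. Over all genes tested, 2 rose and 1 fell with edgeR, and 7 rose and 3 fell with DESeq2, which called more genes in all. Adjusted over the list alone, 9 rose and 3 fell with edgeR. Among the latter, Arntl, Npas2 and Clock were lower, with log2 fold changes of -1.47, -1.18 and -0.31. Per1, Per2 and Dbp were higher, with log2 fold changes of 0.77, 0.72 and 0.88, and Ciart, a repressor of the clock, had 1.05. Nr1d1, which encodes REV-ERBα, stood at 89.6 ± 15.1 CPM in the knockout group and 88.4 ± 19.6 CPM in the controls (SD, n = 5 each), with an edgeR adjusted p of 0.97. The clock list passed the camera test (adjusted p = 7.15e-07) and fry's directional test (adjusted p = 0.00234), but its adjusted p = 0.0677 with an estimated correlation. Its mean log2 CPM was higher in every knockout library than in every control library (exact permutation p = 0.00794, adjusted p = 0.286 over 36 lists). That p of 0.00794 is the smallest the test allows, so the list alone could not pass after adjustment.

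**Figure D2:**
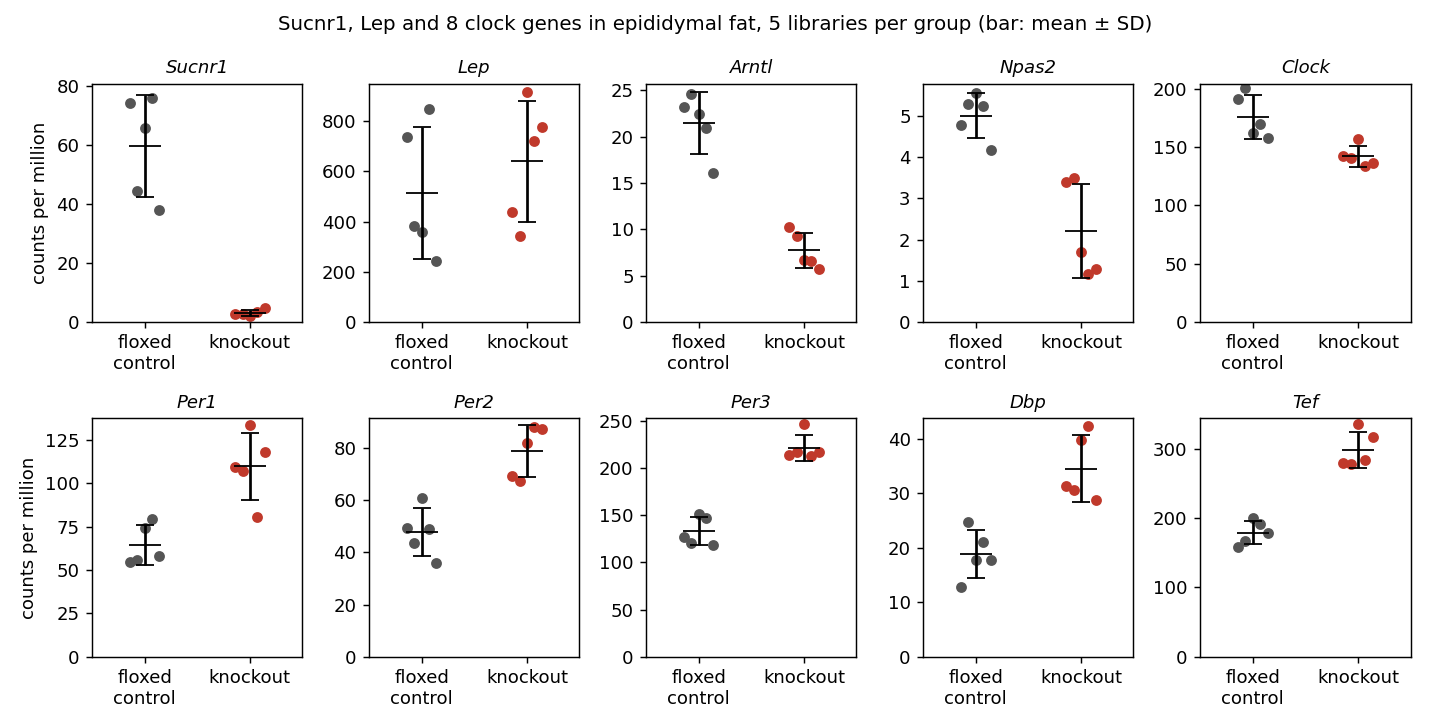
CPM of Sucnr1, Lep and 8 clock genes in each library, with 5 floxed control and 5 knockout libraries per panel; points are libraries and bars show the mean ± SD. Sucnr1 and Arntl were lower and Per3 and Tef higher in every knockout library than in any control library, and Lep overlapped between the groups.

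Lep, which encodes the adipocyte hormone leptin, was not called. It stood at 640 ± 241 CPM in the knockout group and 515 ± 263 CPM in the controls (SD, n = 5 each), a log2 fold change of 0.31 with a standard error of 0.38 (edgeR adjusted p = 0.775). Its sign turned with sample weights (-0.023), with the adipocyte marker score as a covariate (-0.253) and without control libraries 3 and 6 (-0.0256). Among 17 tested adipokine genes, 8 were higher and 9 lower, and none passed over all genes or adjusted over the list alone. The list's median log2 fold change was -0.047 while its mean score differed by 0.002, and camera gave an adjusted p of 0.362.

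Genes of fat synthesis were higher in the knockout group as a list. Of 20 tested genes of fatty acid and triglyceride synthesis, 19 were higher and 1 lower, with a median log2 fold change of 0.64. None passed over all genes, and 12 rose when adjusted over the list alone. They included Mlxipl, which encodes the glucose-responsive factor ChREBP (42.1 ± 6.6 CPM in controls and 61.4 ± 4.3 in knockouts), Lpin1, a phosphatidate phosphatase (523 ± 136 and 924 ± 231 CPM), and Agpat2, an acyltransferase of triglyceride synthesis (112 ± 22 and 188 ± 51 CPM; SD, n = 5 each). The list passed camera (adjusted p = 1.49e-10), with an adjusted p = 0.462 with an estimated correlation. Its mean log2 CPM was 8.324 in knockout library 5, inside the control range of 8.035 to 8.636. In the other knockout libraries it was 8.768 to 9.424.

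Genes of mitochondrial energy metabolism leaned the same way by smaller amounts. All 23 tested genes of the tricarboxylic acid cycle and succinate metabolism were higher in the knockout group, with a median log2 fold change of 0.30, and none passed singly. Sdha, the catalytic subunit of succinate dehydrogenase, had a log2 fold change of 0.39 and Dlst, a subunit of the 2-oxoglutarate dehydrogenase complex, had 0.27. Of 34 nuclear-encoded respiratory chain genes, 32 were higher (median 0.24), and of 13 mitochondrially encoded genes, 11 were higher (median 0.18). These lists passed camera with adjusted p of 9.32e-09, 9.32e-09 and 0.00532, and with an estimated correlation the adjusted p were 0.462, 0.467 and 0.593. With the adipocyte marker score as a covariate, chosen after seeing the data, the tricarboxylic acid cycle list lost its call (adjusted p = 0.0924) and the respiratory chain list had 0.0215, whereas the mitochondrially encoded list had a smaller p (0.000908). That list had 0.000218 without control libraries 3 and 6, and lost its call without knockout library 3 (0.079) or control library 5 (0.0715). Knockout library 5 had the lowest mean log2 CPM of the knockouts for the tricarboxylic acid cycle (7.11) and respiratory chain (6.311) lists. Both values lay inside the control ranges of 6.9 to 7.329 and 6.241 to 6.583.

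Markers of adipocytes were also higher. Of 20 adipocyte identity genes, 19 were higher in the knockout group, and Gpd1 and Acsl1 rose when adjusted over the list alone, with log2 fold changes of 0.95 and 0.81. The list's mean log2 CPM was 10.8 ± 0.18 in the knockout group and 10.4 ± 0.42 in the controls (SD, n = 5 each; exact permutation p = 0.111). Control libraries 3 and 6 had the lowest values. Adipogenic transcription factors (15 of 17 higher), lipolysis genes (16 of 22) and insulin signalling genes (18 of 23) also passed camera, with adjusted p of 0.000144, 0.00173 and 0.0019. With an estimated correlation these 4 lists had adjusted p of 0.467, 0.462, 0.593 and 0.462. Without control libraries 3 and 6, a choice made after seeing the data, the adipocyte identity, adipogenic and insulin lists no longer passed (adjusted p of 0.284, 0.355 and 0.266), and lipolysis turned downward (0.959) and also lost its call without control library 6 alone (0.228). With the adipocyte score as a covariate the adipogenic, insulin and lipolysis lists had adjusted p of 0.937, 0.731 and 0.173. The adipogenic and lipolysis lists share members with that score, which fixes part of this loss.

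Of 22 glucocorticoid and fasting response genes, 15 were higher in the knockout group, and 6 rose when adjusted over the list alone. They included Klf15 (log2 fold change 0.89), Zbtb16 (0.91) and Tsc22d3 (1.00), targets of the glucocorticoid receptor, as well as Per1, which the clock list also holds. Camera gave an adjusted p of 0.0019, and an adjusted p = 0.462 with an estimated correlation. The list's mean log2 CPM was highest in knockout library 6 (6.37), which held liver RNA (4310 CPM of Alb), and that of knockout library 5 (5.40) lay below every control. Without library 6 the score difference went from 0.272 to 0.137, with a camera adjusted p of 0.0216. The member with the largest fold change, Tat, an enzyme of tyrosine breakdown in liver, stood at 62.6 CPM in that library and at most 1.28 CPM elsewhere (exact permutation p = 0.73).

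Endothelial markers were lower in the knockout group. All 20 tested genes were lower, with a median log2 fold change of -0.29, and Cldn5, a tight junction protein of endothelium, fell when adjusted over the list alone, from 75.4 ± 18.4 to 32.9 ± 5.0 CPM (SD, n = 5 each; edgeR adjusted p = 0.103 over all genes). Cldn5 passed over all genes in 8 of 27 alternatives: with DESeq2 (adjusted p = 1.3e-06), sample weights (0.00259), 1 surrogate variable (0.0181), the tissue scores (0.0274) or the adipocyte score (0.0419), without control library 6 (0.00292), and without it and knockout 3 (0.0111) or control 3 (0.0124). Sox18 and Pecam1 had log2 fold changes of -0.69 and -0.34. The list passed camera (adjusted p = 6.11e-07), with an adjusted p = 0.467 with an estimated correlation. Adipose progenitor and fibroblast markers were divided, with 9 higher and 11 lower (camera adjusted p = 0.804).

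Immune and immediate early genes leaned lower. Of 21 immediate early genes, 19 were lower, among them Junb and Nr4a1 with log2 fold changes of -0.45 and -0.87. All 15 tested B and plasma cell genes, 17 of 20 macrophage genes, 18 of 21 T and NK cell genes, 15 of 19 inflammatory cytokine genes and 15 of 20 interferon response genes were lower. Among the inflammatory genes the smallest p and the largest change belonged to Ptgs2, which encodes an enzyme of prostaglandin synthesis (log2 fold change -7.01, edgeR adjusted p = 0.4). It stood at 191 CPM in control library 2 and 1507 CPM in control library 3, the libraries with 807.5 and 5106 CPM of Akr1b7, a gene abundant in the vas deferens, and at most 4.005 CPM elsewhere. Without either library the list kept its camera call (adjusted p of 0.00142 and 0.0112). No member of these 6 lists passed over all genes or adjusted over the list alone. Camera gave adjusted p of 1.44e-05, 6.68e-05, 0.0208, 0.0368, 0.00232 and 0.0494 in that order. With an estimated correlation the adjusted p were 0.462, 0.462, 0.656, 0.607, 0.462 and 0.634. The camera calls of 3 lists were lost under several alternatives, interferon response under 9 (adjusted p of 0.0899 with epididymal and hepatocyte scores, 0.0565 without knockout 3 and control 6, 0.399 without knockout 6 and control 3, and 0.192, 0.196, 0.122 and 0.367 without knockout 3, knockout 6, control 3 or control 5). Macrophage genes lost theirs under 5 (0.105 without knockout 6 and control 3, and 0.261, 0.365 and 0.178 without knockout 3, control 3 or control 4), and T and NK cell genes under 10 (0.0566 with the tissue scores, 0.105 without knockout 3 and control 6, and 0.0683 to 0.191 without knockout 2, 3 or 4 or control 2, 4 or 5). The replicate block ended the calls of all 3 lists (0.0706 for interferon response and for macrophage genes, 0.0811 for T and NK cell genes). Library totals ended those of interferon response (0.0682) and T and NK cell genes (0.1).

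**Figure D3:**
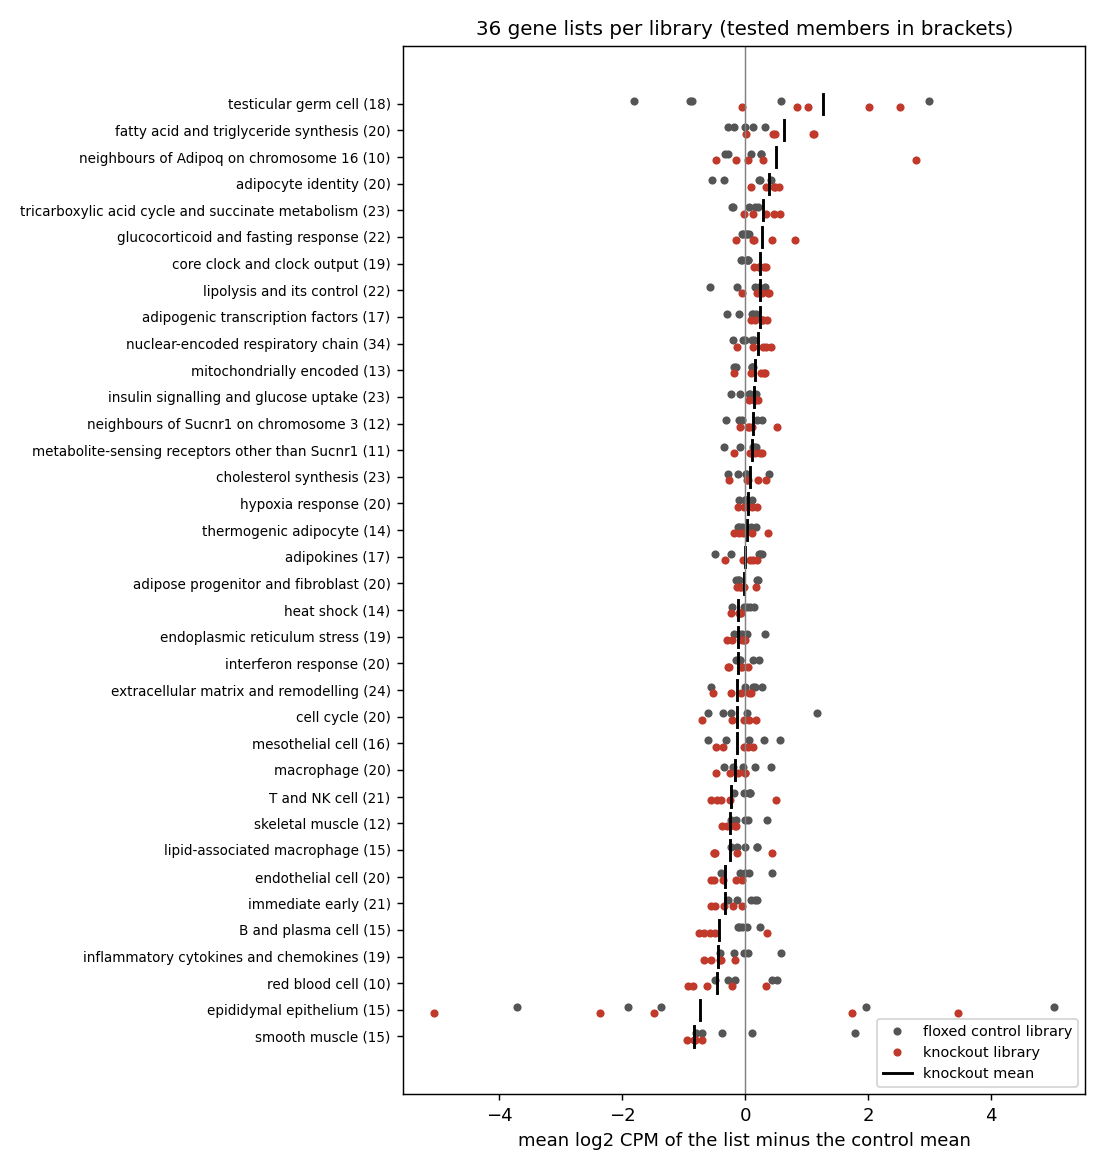
Mean log2 CPM of each of 36 gene lists in each library, drawn as the difference from the control mean; black ticks mark the knockout mean and brackets give the tested members. Knockout and control points separate for the clock list and overlap for most others, and epididymal epithelium and testicular germ cell lists spread over several log2 units within both groups.

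RNA of other tissues was present in several libraries of both groups. Crisp1, a secretory protein of the epididymis, stood at 971 and 3574 CPM in knockout libraries 2 and 3 and at 1049, 2715 and 8572 CPM in control libraries 2, 3 and 6. In the other 5 libraries it ranged from 1.30 to 184 CPM. Akr1b7, a gene abundant in the vas deferens, stood at 5106 CPM in control library 3 and 807.5 CPM in control library 2. Knockout library 6 held 4310 CPM of Alb, the albumin gene of liver, where no other library passed 83.1 CPM. Smooth muscle genes were lower in the knockout group in 14 of 15 cases, and 8 fell when adjusted over the list alone, but Cnn1 stood at 245 CPM in control library 3 and at most 27.7 CPM elsewhere. Testicular germ cell genes were higher in 12 of 18 cases, none past the threshold adjusted over the list alone. Camera gave adjusted p of 0.0021 for smooth muscle and 7.27e-05 for germ cells, and with an estimated correlation the adjusted p were 0.515 and 0.564. The first principal component, with 49.3% of the variance, ran from control library 6 to knockout library 4 and did not separate the groups.

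**Figure D4:**
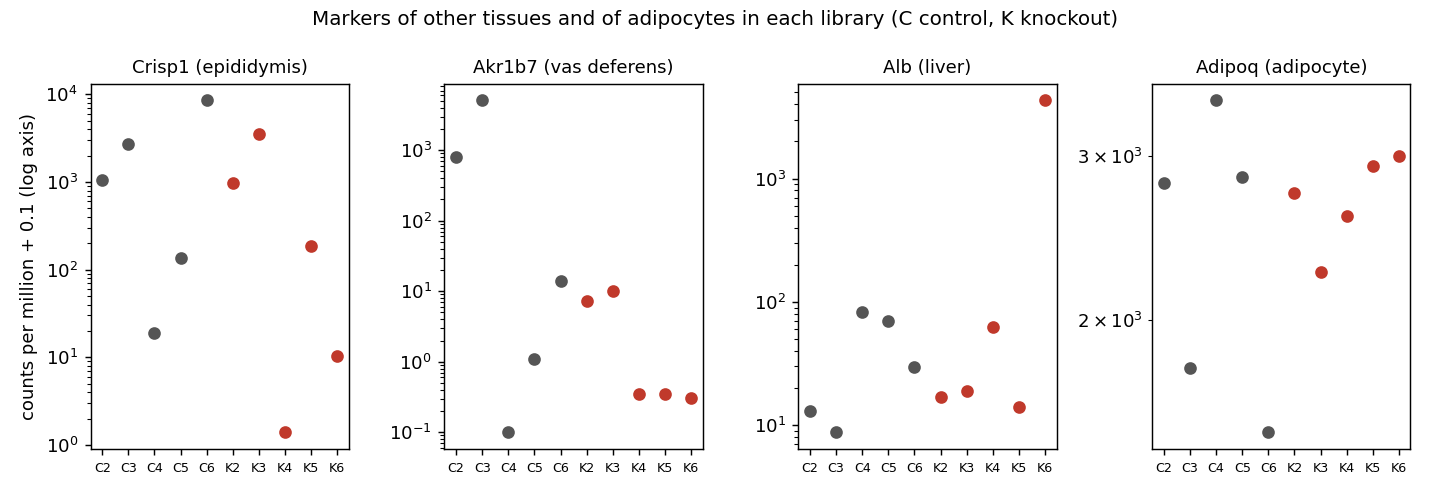
CPM plus 0.1, on log axes, of Crisp1, Akr1b7, Alb and Adipoq in each library; C marks floxed control and K knockout libraries, with the title numbers 2 to 6. Crisp1 was highest in control library 6 (8572 CPM), Akr1b7 in control library 3 (5106 CPM) and Alb in knockout library 6 (4310 CPM).

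In all, 19 of the 36 lists passed camera with a preset correlation, 11 upward and 8 downward. None passed with an estimated correlation, and fry called 1 (the clock list). No list mean passed an exact permutation test after adjustment, though 6 had an unadjusted p under 0.05. The smallest p this test allows is 0.00794, which for the clock list became 0.286 over 36 lists. A list standing alone could therefore not pass. Single libraries moved the mean score difference of several called lists by over 1.5 times. Without control 6, adipocyte identity went from 0.383 to 0.246, lipolysis from 0.235 to 0.093, insulin signalling from 0.143 to 0.086, germ cells from 1.268 to 2.015 and macrophage genes from -0.169 to -0.256. Without control 3, smooth muscle went from -0.827 to -0.38 and macrophage genes to -0.063. Germ cells went to 0.817 without control 4, endothelial genes from -0.328 to -0.218 and interferon response from -0.123 to -0.069 without control 5, and macrophage genes to -0.092 without knockout 3. T and NK cell genes went from -0.227 to -0.145 without knockout 4 and -0.41 without knockout 5, and the mitochondrially encoded list from 0.158 to 0.244 without knockout 5. Lists that did not pass camera included cholesterol synthesis (adjusted p = 0.21), thermogenic adipocyte (0.288), hypoxia response (0.481), endoplasmic reticulum stress (0.149), heat shock (0.129), extracellular matrix (0.138), cell cycle (0.32), metabolite-sensing receptors other than Sucnr1 (0.358), lipid-associated macrophage (0.0678), mesothelial cell (0.819), epididymal epithelium (0.373), skeletal muscle (0.0683) and red blood cell (0.804). In the red blood cell list the median log2 fold change was 0.004 while the mean score differed by -0.459.

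Of the 17 lists that missed camera's threshold, 10 passed under at least 1 of 19 other fits, of which those with marker scores or with 2 libraries removed were chosen after seeing the data. Lipid-associated macrophage genes were lower with a call in 9 fits. Their adjusted p was 0.00156 with the adipocyte score, 0.0403 with the epididymal and hepatocyte scores, 0.0305 with 1 surrogate variable, 0.00303 without control 3 and 6 and 0.0148 without knockout 6 and control 3. It was 0.0236, 0.0204, 0.00243 and 0.036 without control 3, control 6, knockout 5 or knockout 6. Extracellular matrix genes were lower with a call in 8 fits, with adjusted p of 5.52e-05, 0.021, 0.00198 and 0.00303 in the first 4 of these settings and 0.0102 without knockout 3 and control 6, and of 0.00032, 0.0161 and 0.0473 without control 6, knockout 4 or knockout 5. Neighbours of Adipoq on chromosome 16 (adjusted p = 0.0586) were higher with a call in 7, at 0.00412 with the replicate block, 0.0292 with library totals, 0.0231 with the epididymal and hepatocyte scores, and 0.0193 to 0.0451 without control 6 or knockout 2, 4 or 5. All 7 fits held knockout library 6, the library with 4310 CPM of Alb, in which the list's mean log2 CPM was 5.50 against 2.25 to 3.01 in the other knockout libraries, with 225 CPM of Kng1 and 202 CPM of Ahsg, genes expressed in liver. Without that library the list's mean score difference turned from 0.498 to -0.072, and camera gave an adjusted p of 0.277, or 0.418 without it and control 3, still upward.

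Skeletal muscle genes were lower with a call in 6 fits, without control 4 or 5 or knockout 2, 4, 5 or 6 (adjusted p of 0.0232 to 0.0477). Cholesterol synthesis genes were higher with a call in 5, at 0.0482 with the adipocyte score, 0.0159 without control 3 and 6, 0.0116 without knockout 3 and control 6, and 0.0204 and 0.0298 without control 6 or knockout 5. Endoplasmic reticulum stress genes were lower without control 3 (0.0455) and without it and knockout 6 (0.0194). With the adipocyte score, adipokines turned lower (0.0116) and epididymal epithelium genes turned higher (0.00698). Heat shock genes were lower without control 5 (0.0251), and cell cycle genes turned higher without control 3 and 6 (0.0434).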

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

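The outlying values here come from a planned rule, and the tests in the next paragraphs were chosen or written down only after the results were seen, those on other splits of the libraries included. The tests of adipocyte share took their present form after other forms had been run: camera with the adipocyte score as a covariate, counts of genes beyond 2 standard errors, and differences between list scores. In 268 tests of the highest or lowest library within a group of 5 (Dixon's ratio, limit 0.71), 15 values stood apart, and chance gives about 5%, or 1 in 20. Among called genes these were Zfp949 in knockout library 3 (ratio 0.775) and Per3 in knockout library 4 (0.868), both the highest of their group. In knockout library 6 the highest values were those of Acrv1 (0.754), Kng1 (0.752), Kng2 (0.783) and Akap3 (0.839), and of the lists of B and plasma cells (0.776) and Adipoq neighbours (0.766). Control library 3 was highest for Acta2 (0.806) and Fcgr1 (0.712). Control library 6 was lowest for Foxo1 (0.773) and highest for Dnajb3 (0.868). Control library 2 was lowest for Nr1d2 (0.799), control library 4 highest for Klf15 (0.723), and knockout library 2 lowest for the heat shock list (0.783).

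Among 100 splits of the libraries into 5 and 5, the real one included, 3 gave at least 10 called genes, a share under 0.05. This counts against chance for the number of genes but does not exclude it. The limit was set after the results were seen, and the 10 genes include Sucnr1, the targeted gene. The highest other split gave 363 genes. It set knockout libraries 2 and 3 with control libraries 2, 3 and 6. These are the libraries with 971 to 8572 CPM of Crisp1, against 1.30 to 184 CPM in the others. That split follows epididymal RNA, a structure of the samples other than genotype. For gene lists chance is not argued against: 9 of the 100 splits gave at least the 19 lists of the real split, and the highest other gave 24.

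The genes with an unadjusted p under 0.001 gathered on chromosome 9, where they lie between 51765337 and 107352422. The real split, with 53 such genes, had a hypergeometric enrichment p of 2.66e-05 for chromosome 9. A chromosome was as enriched in 2 of 100 splits, the real one included. The smallest enrichment p of the others was 5.05e-06, in a split with 6 such genes. Many other splits had few such genes or none, and a chromosome with fewer than 2 was not scored as enriched. Those splits could hardly match the real one, so this count cannot decide on chance. RNA of epididymis and liver is argued against, since all 5 chromosome 9 calls passed with both marker scores as covariates. Loss of reads from a non-reference segment in knockout libraries is argued against as the whole cause. Of the 12 genes, 5 were higher in knockout. Loss of reads in control libraries, which would make genes look higher in knockout, was not tested. A chromosome segment inherited with the Cre driver or the floxed line may be a candidate explanation and stays open: windows of 2, 5, 10, 20 and 40 Mb held more of the 12 genes than random chromosome 9 genes did (permutation p from 2e-04 to 0.013 over 10000 draws), while the median gap to the nearest gene gave a permutation p of 0.14, and the first window size was chosen with the positions known. An effect of the receptor on these genes was not tested apart from this.

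For the clock genes, RNA of epididymis and liver is argued against, as Arntl, Per3 and Tef, 3 of 3, passed with both scores as covariates. A lower share of adipocytes in control libraries is argued against as the whole cause of the list's shift, since with the adipocyte score as a covariate the list score still differed by 0.234 (SE 0.053), camera gave an adjusted p of 1.1e-05 and all 12 genes that passed adjusted over the list alone stayed beyond 2 standard errors in the same direction and kept a median share of 0.99 of their log2 fold change. These 12 genes were picked by their group difference in the same libraries. Over all 19 members the median log2 fold change was 0.42 before and after. Per1, Per2 and Per3 shrank from 0.765, 0.719 and 0.735 to 0.607, 0.501 and 0.619, while Dbp went from 0.877 to 0.963. In the fit with the adipocyte score, Arntl had a log2 fold change of -1.51 (SE 0.21) against -1.47 (SE 0.18) without it, and Tef 0.67 (SE 0.10) against 0.74 (SE 0.09). Both lost their calls (edgeR adjusted p of 0.0703 and 0.0832) as the errors grew, with a smaller fold for Tef, and of the 3 called clock genes Per3 alone kept it (0.0295). A different time of day or feeding state at collection could move these 12 genes, and it cannot be told apart from the knockout because no label gives a collection time.

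For the higher fat synthesis and respiratory genes and the lower endothelial genes, a lower share of adipocytes in control libraries was weighed with the adipocyte score in the model. For endothelial genes the score difference did not shrink, at -0.486 (SE 0.184). All 20 genes stayed lower, and their median log2 fold change went from -0.29 to -0.44. The endothelial score minus the progenitor score, which a lower share would leave alike, gave an exact permutation p of 0.127. These values cannot decide the question, because the adipocyte score does not measure adipocyte share alone. It was lowest in control libraries 6 and 3 and knockout library 3 (9.893, 10.098 and 10.531), with 8572, 2715 and 3574 CPM of Crisp1. In control library 6 the endothelial score was also the lowest of the controls (5.552). For fat synthesis the list kept its camera call with the preset correlation, with the adipocyte score (adjusted p = 0.000307) and without control libraries 3 and 6 (4.68e-06). Camera with the preset correlation also called many lists in other splits of the libraries. A lower share of adipocytes as the whole cause therefore cannot be judged from these calls. It stays open because the score difference of 0.386 (SE 0.254) lay within 2 standard errors of 0, 5 of the 12 genes that passed adjusted over the list alone stayed beyond 2 standard errors with a median share of 0.58 of their log2 fold change kept, the fat synthesis minus the adipocyte identity score was 0.251 (exact permutation p = 0.278), and a change of expression within adipocytes, which would move the markers too, cannot be told apart from a changed share here. The values of the other lists are consistent with a lower share, with score differences of 0.091 (SE 0.114) for the tricarboxylic acid cycle, which lost its camera call (adjusted p = 0.0924), and 0.101 (SE 0.13) for the respiratory chain, which kept it (0.0215), and in each the genes beyond 2 standard errors went from 10 to 0.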

How the results depend on the processing

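The alternatives with marker scores as covariates or with 2 libraries removed were chosen after seeing the data. Sucnr1 kept its direction and its call under every alternative run. The count of 10 called genes became 211 with DESeq2 (126 higher, 85 lower), 27 with sample weights and 16 with 1 surrogate variable, each sharing all 10. It was 16 without knockout 3 and control 6 (9 shared), 4 without knockout 6 and control 3 (3 shared) and 6 without control 3 and 6 (5 shared). Leaving out 1 library gave 3 to 18. It gave 3 without knockout 3, knockout 4 or control 3, 4 without knockout 2, knockout 5 or control 2, 6 without knockout 6 or control 5, 8 without control 4 and 18 without control 6. The cause was not tested. The other scalings and filters gave 10, the same genes, except 9 with upper-quartile scaling (without Ppm1m), and limma-voom gave 9 (without Adamts4). The epididymal and hepatocyte scores gave 13 (10 shared) and the adipocyte score 10, of which 7 were shared (Gsta4, Arntl and Tef lost).

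The title numbers 2 to 6 occur in both groups. With the number as a replicate block, 4 genes were called, all among the 10. Per3, Tef and Ppm1m (edgeR adjusted p = 0.132 each), Gsta4 (0.0541), and Abhd14b and Adamts4 (0.228 each) no longer passed. Correlations of deviations between same-numbered libraries were 0.377, -0.113, 0.632, 0.436 and -0.096. Of the knockout libraries, 2 of 5 correlated best with their own number, so the numbers were not taken as pairing. As some correlations were well above 0, these values cannot exclude a batch shared by number.

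Lep, not called anywhere, turned to -0.023 with sample weights, -0.0256 without control 3 and 6 and -0.253 with the adipocyte score. Nr1d1, also never called, turned to -0.0293 with library totals, -0.133 with sample weights, -0.122 without knockout 3 and control 6, -0.178 without control 3 and 6 and -0.164 with the adipocyte score, and ranged from -0.0959 to 0.117 with 1 library left out. The 19 lists became 0 with an estimated correlation and 1 with fry. With the adipocyte score as a covariate, adipogenic factors (adjusted p = 0.937) and lipolysis (0.173) turned downward, and lipolysis also without control 3 and 6 (0.959). Both lists share members with that score, such as Cebpa (adipogenic) and Plin1 and Pnpla2 (lipolysis), so the design fixes part of their change with it. The adipocyte list set against its own score turned downward (0.717), which that design largely fixes. The cause was not tested. At depths of 24182798 to 30603326 counts and the spread seen here, 8% of simulated 1.5-fold changes were recovered, so small changes were mostly not detectable.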

Other observations

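Of the genes beside Adipoq on chromosome 16, a list fixed before the data were examined, Eif4a2 and Rfc4 rose when adjusted over the list alone. Eif4a2, a translation initiation helicase, stood at 505 ± 38 CPM in the knockout group and 378 ± 37 CPM in the controls. Rfc4, a subunit of the clamp loader of DNA replication, stood at 4.67 ± 0.48 and 3.17 ± 0.46 CPM (SD, n = 5 each). Both groups separated without overlap for each gene, and neither passed over all genes with edgeR (adjusted p of 0.318 and 0.36). With DESeq2, which called more genes in all, both passed (adjusted p of 0.000687 and 0.0186). The 2 genes overlap at their ends on opposite strands, so reads there cannot be assigned without the strand setting. Kng1 and Kng2, in the same list, were high in knockout library 6 alone, the library with 4310 CPM of Alb.

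Adora1, the adenosine A1 receptor that restrains lipolysis in adipocytes, rose among 11 metabolite-sensing receptors when adjusted over the list alone, from 70.2 ± 12.7 to 118 ± 26 CPM (SD, n = 5 each; edgeR adjusted p = 0.31 over all genes). In the thermogenic list Letmd1 and Ppara rose in the same sense, with log2 fold changes of 0.31 and 0.88, while Ucp1 was at most 0.923 CPM in any library. Adm, a hypoxia-induced peptide hormone, fell from 15.9 ± 2.6 to 10.4 ± 1.1 CPM adjusted over the list alone. Anxa3 fell likewise among progenitor markers, with a log2 fold change of -0.34.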
